A study of Caenorhabditis elegans with 4 samples.

How the data were processed

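The series measured LIN-61 occupancy by ChIP-seq in N2 L3 larvae. Per the labels' protocols, frozen and ground worms were fixed with EGS, a protein crosslinker, for 20 minutes, then 10 minutes longer after formaldehyde was added, the chromatin was sonicated, and ChIP or input DNA was made into libraries with PCR amplification and sequenced on Illumina instruments. Samples were grouped by their titles into 2 LIN-61 ChIP libraries and 2 input DNA libraries, with the replicate number from the same title.

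Per the file headers, the authors' peak lists are on genome build WormBase WS220 and the peaks are binding sites called with MACS. The MACS version and threshold, the control library, the aligner and the read filters are not given in the sources used here. The authors deposited 1 list per ChIP library and 1 list for the series, and how the last was made is not stated. Each deposited peak has a start, an end and a score. The quantity behind the deposited score is not named; its lowest value was 1.32 in the combined list, 1.32 in replicate 1 and 1.31 in replicate 2, close to 1.30, the negative decimal logarithm of 0.05. The score was therefore used to rank peaks and to compare medians within a list, and between lists only in the correlations over pairs of peaks, where Pearson's r takes the scores as they stand. Because read counts were not part of these lists, depth is unknown, and a list with fewer peaks may come from a shallower library. Wilson intervals on shares of peaks cover counting error only and treat peaks as independent, which neighbouring peaks need not be.

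Coordinates count from 1. The right end of each chromosome was taken as the last base of any peak in the 3 lists, which was a replicate 1 peak on each nuclear chromosome. Peaks on the 6 nuclear chromosomes were compared, and the 2 peaks on mitochondrial DNA in replicate 1 were set aside. A peak counted as shared when at least 1 bp overlapped. In the circular permutation (rotation) tests, all peaks of a list on a chromosome were moved by the same random distance, with the ends joined. The distance was drawn separately for each chromosome, 10000 times. Such shifts keep widths and clusters. The replicate overlap was tested one-sided and the arm share and the arm-centre differences two-sided. Adjustment over the 6 chromosomes was by Benjamini-Hochberg. Score correlations over pairs of overlapping peaks, each peak used once, were tested with 100000 permutations. X against the 5 autosomes was tested by exact permutation over chromosomes. The named regions were chosen by a rule: the 10 combined peaks with the highest score that overlap a peak of both replicates.

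The tests, the alternatives to them and the rule for named regions were written down before the data were examined, except where the text says otherwise. The comparison of width and score between arms and centres, the split by score, the comparison of peaks with and without a partner, the arm test of each chromosome, the 100-kb windows and the widest peaks were added after the data were seen. The alternatives fixed beforehand were other overlap rules, the stronger part of each list, equal list sizes, rotation in 1-Mb blocks, other arm limits, covered length in place of peak number, combined peaks with both replicates, and each replicate list alone. Tests of the share of peaks at promoters, of repeats, of 16 fixed gene lists and of classes of RNA genes had also been fixed but were not run, since they needed an annotation of build WS220 and the gene table used for names is of WBcel235. For the same reason the rule's gene names were dropped and regions are given by coordinate. The overlap and rotation procedures were tested on simulated data built from the widths and chromosome counts of the replicate lists. For the replicate overlap, the shared state was recovered for 100% of 11741 simulated peaks with 60% planted as shared, and 3 of 60 independent pairs were called at a threshold of 0.05. For the arm share, 80.1% was recovered where 80% was planted, and 5 of 60 evenly placed lists were called. The planted shared peaks were exact copies at the same place, so full recovery checks the code only. The independent pairs and evenly placed lists used a subset of the peaks and fewer rotations than the tests of the real lists. The simulated peaks were placed independently, without the clustering of the real ones. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.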

Results

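LIN-61 binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Caenorhabditis elegans of the laboratory strain N2, collected as L3 larvae grown at 20 degrees Celsius. LIN-61 is a nuclear protein with MBT repeats that binds histone H3 methylated at lysine 9, a mark of heterochromatin, and its loss contributes to the synthetic multivulva phenotype. The series holds 2 ChIP libraries made with a rabbit polyclonal antibody to LIN-61 and 2 input DNA libraries from the same stage. The data analysed here are 3 peak lists on genome build WS220: 11744 peaks for ChIP replicate 1, 9436 peaks for ChIP replicate 2 and 13662 peaks in a combined list for the series. No peak list of an input library was analysed here, so the comparison of ChIP with control rests on the authors' peak calls. The lists give no read counts, and the depth of each library is therefore unknown. The labels do not say whether the replicates came from separate worm cultures, so the spread between them may be technical.

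The first question was how far the peaks of the replicates lay at the same sites. In replicate 1, 6935 of 11742 nuclear peaks (59.1%, 95% Wilson interval 58.2 to 59.9) had a partner in replicate 2 that overlapped by at least 1 bp. In replicate 2, 8023 of 9436 peaks (85.0%, 84.3 to 85.7) had a partner in replicate 1. When the replicate 2 peaks were shifted together around each chromosome, the mean shares were 9.99% and 12.9%, and the highest of 10000 rotations reached 17.4% and 23.6%. Both observed shares lay above every rotation (one-sided circular permutation test, p = 1e-04 for each, the smallest value the rotations can give). The rotations ask only whether peak positions coincide, not whether the shared peaks are specific to LIN-61. Shifting peaks only within blocks of 1 Mb, which keeps the density of each region, raised the mean shares to 14.8% and 19.4% and left p at 1e-04. Under the stricter demand that 50% of both peaks overlap, the share of replicate 2 peaks with a partner was 50.6%.

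Strong peaks were shared and weak peaks often were not. Each list was split into 10 equal parts by the score that the authors' peak caller gave each peak. In the strongest part, 99.6% of replicate 1 peaks and 99.5% of replicate 2 peaks had a partner. In the weakest part, the shares were 24.0% in replicate 1 (95% Wilson interval 21.6 to 26.5) and 65.0% in replicate 2 (61.9 to 68.0). Replicate 1 peaks with a partner had a median score of 13.14 and a median width of 475 bp, against 4.80 and 220 bp for those without one. In replicate 2 the medians were 8.70 and 338 bp with a partner and 4.64 and 195 bp without. A wide peak reaches an overlap of 1 bp more easily, and no rotation share was computed for each part. The roles of score and width were therefore not separated. Over 6612 pairs of overlapping peaks, the scores of the replicates were correlated across peaks, with Spearman's rho of 0.72 and Pearson's r of 0.80 (two-sided permutation test, p = 1e-05 for each, the smallest value that 100000 resamples can give). Peaks are not independent replicates, so this p concerns the ranking of sites within these libraries. At a coarser scale, the peak-covered length of 1005 windows of 100 kb was correlated between the replicates with rho of 0.93, and the highest of 1000 rotations gave 0.41 (one-sided circular permutation test, p = 0.001, the smallest value possible).

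**Figure D1:**
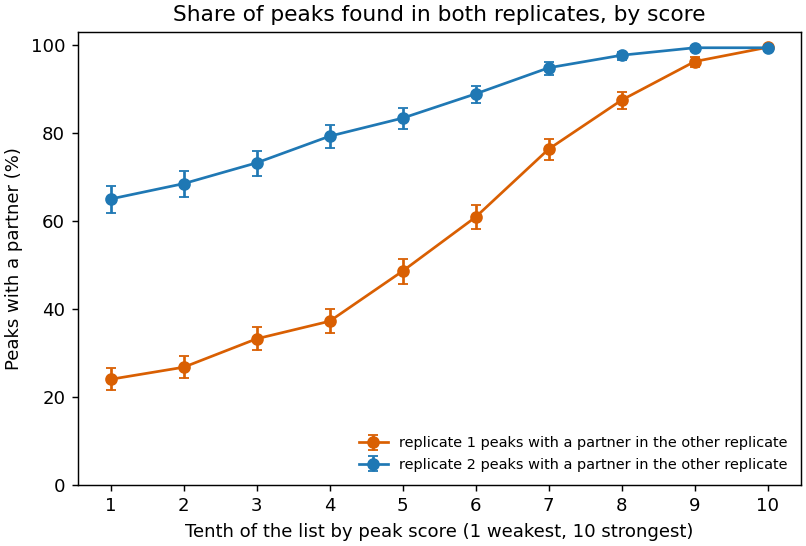
Share of peaks (%, vertical axis) with a partner in the other replicate, for each of 10 parts of the list ordered by peak score from weakest to strongest (horizontal axis), with 95% Wilson intervals as bars. Replicate 1 (orange) climbs from 24.0% to 99.6% and replicate 2 (blue) from 65.0% to 99.5%.

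The combined list was compared with the replicate lists to learn what kind of list it is. Of its 13662 peaks, 6194 (45.3%, 95% Wilson interval 44.5 to 46.2) overlapped a peak of both replicates, 3621 (26.5%) overlapped replicate 1 only and 1074 (7.86%) overlapped replicate 2 only. The remaining 2773 (20.3%) overlapped neither. Peaks supported by both replicates had a median combined score of 20.39 and a median width of 645.5 bp. Those found in neither replicate had a median score of 3.93 and a median width of 186 bp. In the other direction, 92.6% of replicate 1 peaks and 98.3% of replicate 2 peaks overlapped a combined peak. The share in both replicates fell to 29.0% when 50% of the combined peak had to be covered, and it was 82.8% among the stronger part of the list at or above the median score.

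LIN-61 peaks were concentrated in the autosome arms. The arms of C. elegans autosomes are known to be rich in repeats and in histone H3 methylated at lysine 9, while the centres hold more of the broadly expressed genes. With the arms taken as the outer parts that together make up 66.7% of each chromosome, 10781 of 12798 autosomal combined peaks (84.2%, 95% Wilson interval 83.6 to 84.9) were centred in an arm. Rotating the peaks around each chromosome gave 66.6% on average (two-sided circular permutation test, p = 0.001). The share was 85.5% in replicate 1 and 86.9% in replicate 2, a mean of 86.2% ± 1.03 (SD, n = 2). With narrower arms that together make up 50% of the length, the share was 73.4% (circular permutation test, p = 1e-04). No single chromosome passed the rotation test after adjustment over the 6 chromosomes, the lowest adjusted p being 0.1524 for chromosome III, although on each of them more than 78% of the combined peaks lay in the arms.

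The density of peaks in each arm differed from chromosome to chromosome, in the same order in both replicates. On chromosome III, the left arm held 294 combined peaks per Mb, the right arm 247 and the centre 93.6. Chromosome I had 289, 227 and 101 peaks per Mb in these parts. On chromosome IV, the left arm held 238 peaks per Mb and the right arm 113, against 62.9 in the centre. Chromosome V was the opposite way round, with 112.3 in the left arm, 166 in the right arm and 56.6 in the centre. The arms of chromosome II held 161 and 177 peaks per Mb and its centre 62.0. In replicate 1, the left arm of IV had 2.38 times as many peaks as the right arm, and in replicate 2 2.52 times as many. The right arm of V had 1.61 times as many as the left in replicate 1 and 1.68 times in replicate 2. These differences between arms were not tested. Shifting a clustered set of peaks around a chromosome can create such differences by itself, and how often it gives ones as large was not counted.

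**Figure D2:**
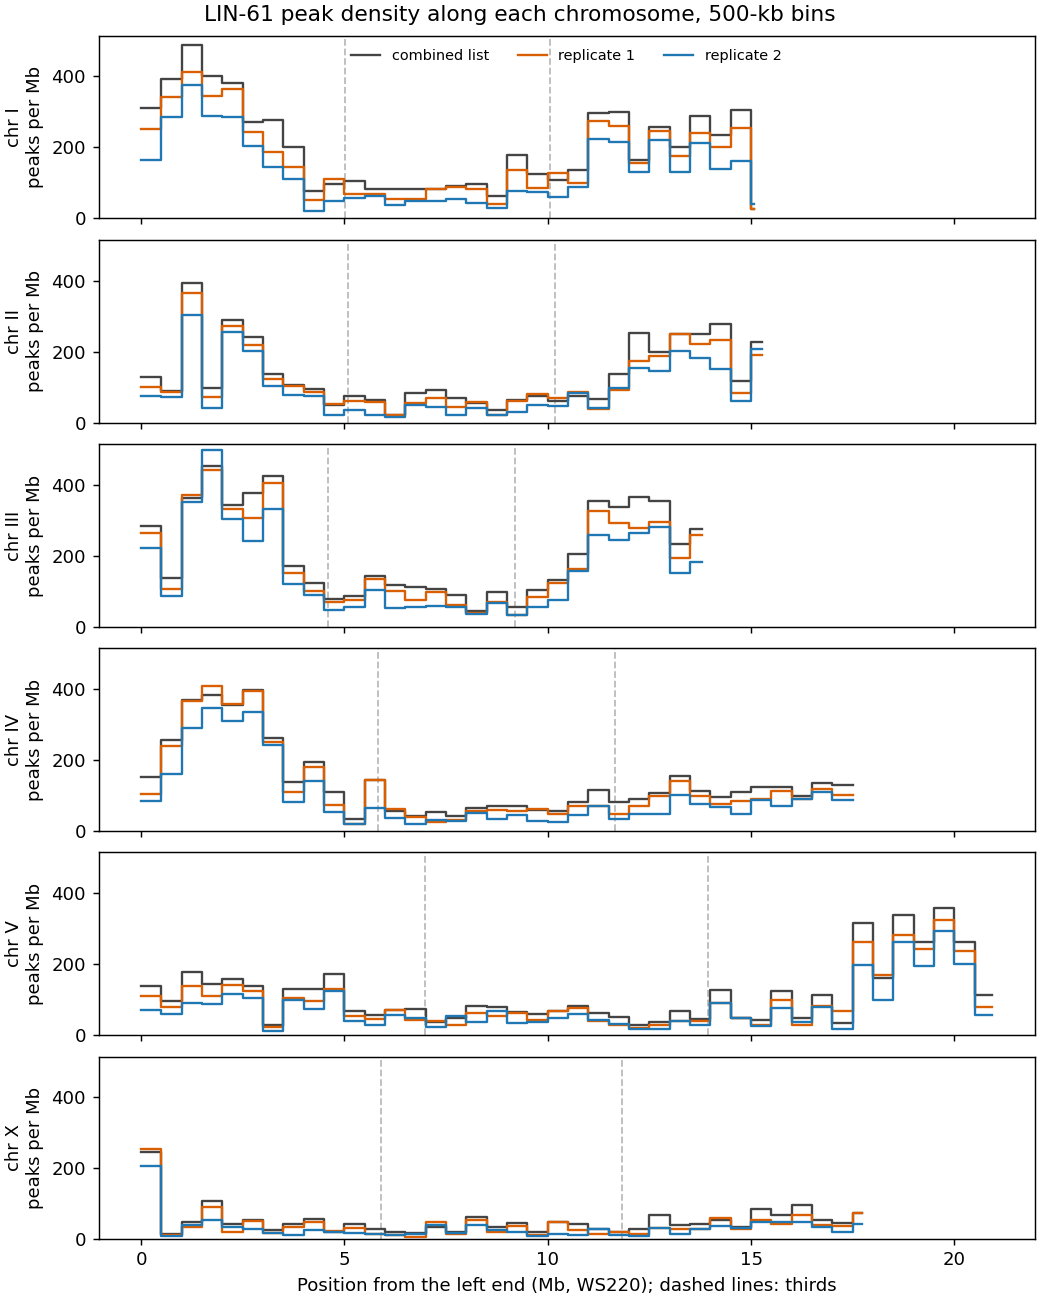
Peaks per Mb (vertical axes) in 500-kb bins along chromosomes I, II, III, IV, V and X (horizontal axis, Mb from the left end, WS220) in the combined list (grey), replicate 1 (orange) and replicate 2 (blue); dashed lines divide each chromosome into its 2 arms and its centre. Peaks are dense in the arms of the autosomes, in the left arm more than the right on IV and in the right arm more than the left on V, and sparse on X apart from its left end.

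Arm peaks were also wider and stronger than centre peaks. In the combined list the median width was 351 bp in the autosome arms and 287 bp in the centres (difference 64 bp, two-sided circular permutation test, p = 0.0005). The median score was 8.97 in the arms and 6.71 in the centres (circular permutation test, p = 0.0013). The width difference was 58 bp in replicate 1 (circular permutation test, p = 0.0012) and 36 bp in replicate 2 (p = 0.0245). The score difference was 2.08 in replicate 1 (circular permutation test, p = 0.0125) and 1.41 in replicate 2, where it did not pass the test (p = 0.0817).

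The X chromosome, which in this organism differs from the autosomes in chromatin, had the lowest density of LIN-61 peaks. The combined list had 48.8 peaks per Mb on X, against 111.7 on V, 133 on II, 138 on IV, 206 on I and 211 on III. The ratio of X to the autosome mean was 0.30 in the combined list, 0.28 in replicate 1 and 0.26 in replicate 2, a mean of 0.27 ± 0.0099 (SD, n = 2) over the replicates. Peaks covered 2.29% of X and between 6.17% (V) and 14.2% (III) of the autosomes. X was the lowest of the 6 chromosomes in each of the 3 lists. An exact two-sided permutation test over chromosomes gave p = 0.1667, which is the smallest value that 1 chromosome against 5 allows, so this comparison cannot pass a threshold of 0.05. Of the 178 windows of 100 kb on X, 23 held no peak in the combined list, 41 in replicate 1 and 46 in replicate 2. Over all 1005 windows, X included, the counts were 41, 69 and 92.

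**Figure D3:**
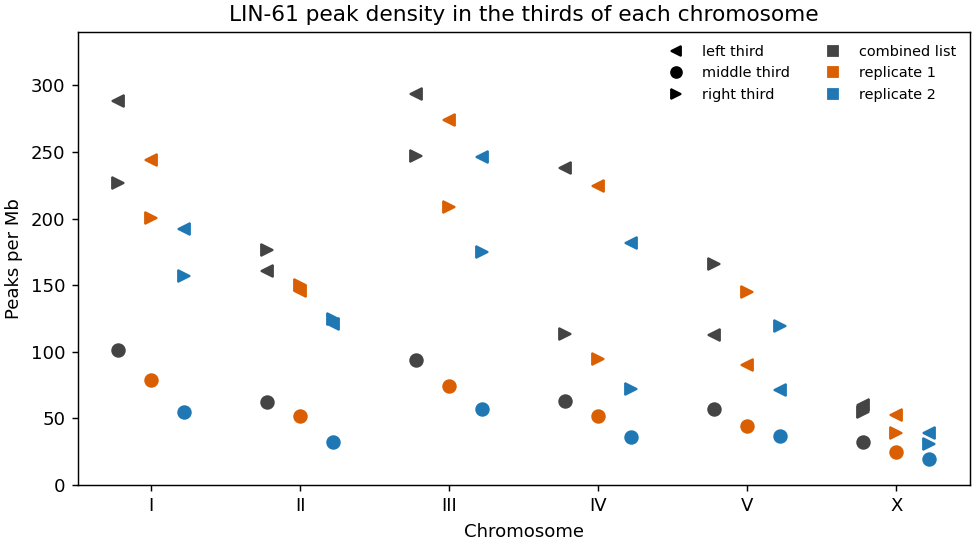
Peaks per Mb (vertical axis) in the left arm (left-pointing triangles), centre (circles) and right arm (right-pointing triangles) of each chromosome (horizontal axis), for the combined list (grey), replicate 1 (orange) and replicate 2 (blue). On every chromosome of every list the centre is lowest. Each part of X lies below the same part of every autosome, with 31.8 combined peaks per Mb in its centre against 56.6 or more in the autosome centres.

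The strongest sites, the 10 best-scoring peaks with both replicates, lay in autosome arms, as did 87.5% of all autosomal combined peaks with both replicates. Of the 10 combined peaks with the highest score that overlapped a peak of both replicates, 6 lay on the left arm of chromosome III, and the others on the left arms of I and IV and the right arms of II and V. Whether so many on 1 arm exceeds chance was not tested for these sites. The highest score, 157.99, belonged to a peak of 2366 bp at chromosome III, 1615117 to 1617482, which was also ranked 1 by its best-scoring peak in both replicates. Its neighbour at 1618940 to 1619373 was 434 bp wide with a score of 157.67, and ranked 3 in replicate 1 and 6 in replicate 2. Other sites of the set on III were a 10561 bp peak at 1512863 to 1523423, a 5541 bp peak at 2146208 to 2151748, a 4205 bp peak at 1038858 to 1043062 and an 8377 bp peak at 1933104 to 1941480, with scores of 149.44 to 152.17. The replicate lists broke these wide peaks into pieces: the 10561 bp peak corresponded to 5 peaks in replicate 1 and 7 in replicate 2. Outside III, the sites were chromosome I, 107780 to 109004 (score 146.65), chromosome II, 14241519 to 14244411 (146.65), chromosome V, 20422239 to 20424844 (146.65) and chromosome IV, 2254891 to 2257353 (145.35). The best peaks over these 10 sites ranked between 1 and 14 in replicate 1 and between 1 and 36 in replicate 2. The genes at these positions are not given, since no annotation of build WS220 was used here.

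Peaks also formed dense tracts. The 100-kb window with the highest covered length was chromosome III, 1500001 to 1600000, where peaks covered 78.8% of the sequence in the combined list, 75.1% in replicate 1 and 57.1% in replicate 2, ranking 1 in both replicates. In the combined list it was followed by chromosome I, 2000001 to 2100000 (59.5%), chromosome III, 1800001 to 1900000 (59.1%) and chromosome III, 2100001 to 2200000 (54.3%). In both replicates the window at 1800001 to 1900000 on III ranked 2, and the one on I ranked 3 in replicate 1 and 5 in replicate 2. The widest single peak spanned 25119 bp on chromosome II, 15197651 to 15222769, near the right end, and the matching peak of replicate 1 spanned 25332 bp. In replicate 2 this stretch held 17 separate peaks, the longest of 5237 bp. On X, a peak of 14764 bp lay at 16929576 to 16944339 and was the widest of replicate 2, at 13427 bp.

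**Figure D4:**
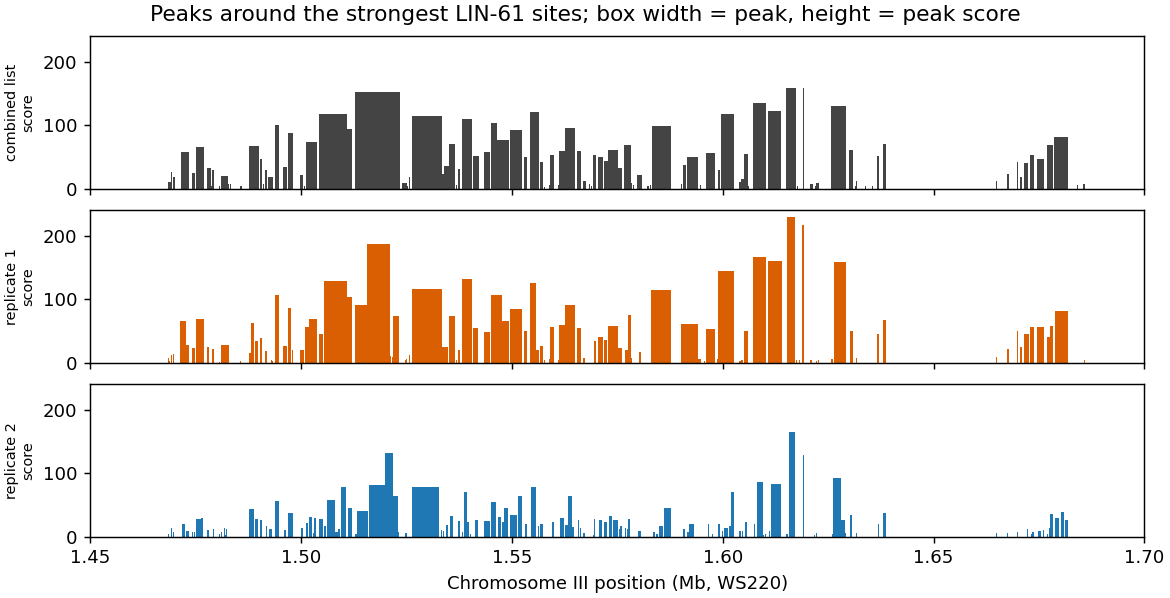
Peaks on chromosome III around its strongest peak (horizontal axis, Mb, WS220) in the combined list (grey), replicate 1 (orange) and replicate 2 (blue); the width of each box is the peak and its height the peak score (vertical axes), which is not on a common scale between lists. The peak with the highest score in all 3 lists lies near 1.62 Mb.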

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

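The tests of merged peaks and of width and score in arms against centres were chosen only after the results were seen. The replicate overlap exceeded the rotations under every alternative run (circular permutation test, p = 1e-04 in each): the share of replicate 1 peaks with a partner ranged from 40.6% with 50% of both peaks overlapping to 68.2% with peaks within 1 kb merged, and that of replicate 2 peaks from 50.6% to 85.9%, the latter in the stronger part of each list. The score correlation was 0.77 for pairs with 50% reciprocal overlap and 0.68 in the stronger part. The composition of the combined list depended on the setting. The share in both replicates, 45.3%, moved to 29.0% where 50% of the combined peak had to be covered and to 82.8% in its stronger part, and the share in neither, 20.3%, moved to 26.7% and 1.16%. A stricter overlap lowers the share in both by construction; the cause of the shift with the score was not tested. The arm share stayed above its expectation under all alternatives run (circular permutation test, p between 1e-04 and 0.0028). For the narrower arms, which make up 50% of the length, it was 73.4%. With arms of 66.7% of the length, it went from 80.5% for merged peaks to 87.5% among combined peaks with both replicates. In the list of each replicate alone it was 85.5% and 86.9%, the values already given above. The ratio of X to autosome density lay between 0.23 for covered length and 0.42 for merged peaks. In the list of each replicate alone it was 0.28 and 0.26, again the values given above. The test of this ratio cannot pass the threshold under any setting. The difference in median score between arms and centres passed the test in the combined list but not in the replicate 2 list alone (1.41, circular permutation test, p = 0.0817). The cause was not tested. A replicate list alone cannot be used for the overlap, the score correlation or the composition, which need both. No paired analysis was possible because the input libraries, which share the replicate numbers of the ChIP libraries, have no peak list analysed here, which leaves no values to pair. The promoter, repeat, gene list and RNA gene alternatives were not run, for want of an annotation of the same build. With replicate 1 reduced to as many of its strongest peaks as replicate 2 has, the shares were 67.3% and 80.1%. Depth is unknown, so these lists do not show whether replicate 1 sites with no partner lie under the threshold in replicate 2.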

Other observations

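All tests in this part were chosen after the patterns they concern had been seen. The left end of X, which carries the meiotic pairing center of that chromosome, stood out from the rest of X in all 3 lists. This held for its first 500 kb, with 244 peaks per Mb in the combined list, 252 in replicate 1 and 206 in replicate 2, while the next 500 kb had 12, 10 and 8 peaks per Mb. Together this leftmost 1 Mb held 128 of 864 X peaks in the combined list (14.8%), 131 of 681 in replicate 1 (19.2%) and 107 of 522 in replicate 2 (20.5%). The median 1-Mb window of X held 42.5, 34.5 and 20.5 peaks, and the next highest held 76, 62 and 47. In the combined list, the densest 1-Mb window of the other chromosomes lay in an arm as well: 1 to 2 Mb on I (445 combined peaks), on III (407) and on IV (375, where 1 other window held as many, and in replicate 2 another held 322 against 317), 2 to 3 Mb on II (264) and 19 to 20 Mb on V (309). None of these windows was tested.

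The strongest sites gathered on the left arm of chromosome III. Of the 137 combined peaks in the top 1% by score, 48 lay there, against 9.88% of all combined peaks; in replicate 1 it was 36 of 121 and in replicate 2 37 of 95. To keep the order of scores along the genome, they were shifted along the ordered peaks in all 13662 ways, and the highest count in any of the 18 arms and centres was taken at each shift. A share of 0.052 of the shifts gave as many, so chance cannot be excluded. The share was 0.17 in replicate 1, 0.038 in replicate 2, under the threshold of 0.05, and 0.072 for the top 5% of the combined list.

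X had fewer peaks per Mb than any autosome in all 3 lists. If X differed only in its arms, its centre should match the autosome centres, but it had 24.4 peaks per Mb in replicate 1 (autosome centres 43.9 to 78.8) and 19.1 in replicate 2 (32.4 to 56.6), and the higher of the ratios to the autosome mean was 0.44, which argues against it. If X sites are weaker and more of them miss the threshold, a candidate explanation, X should lack strong peaks most: the ratio of X to autosome density was 0.36 in the weakest of 4 equal parts of the combined list by score and 0.20 in the strongest, a quotient of 0.57 (95% interval 0.47 to 0.70 from peak counts alone), which goes that way. It meets the bound of 0.67 first set for it, but the demand that the whole interval do so, added once the value was known, is not met, and it is left open. In the top 1% by score, the replicates went opposite ways, on few peaks. X held 9 of 121 such peaks in replicate 1 (7.44%, against 5.80% of that list). In replicate 2 it held 3 of 95 (3.16%, against 5.53%). The lower X dose of any males in these mixed-sex populations, a biological difference, was not tested and stays open.

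Replicate 1 alone had peaks at chromosome tips and on mitochondrial DNA. It had peaks starting at base 1 on 5 chromosomes (I, II, IV, V and X, scores 1.69 to 20.07) and 2 mitochondrial peaks (scores 5 and 75.49), while replicate 2 had neither and its first peaks began between 2163 bp on I and 32022 bp on II. At the right ends, the last peak of replicate 1 lay beyond those of both other lists on each nuclear chromosome. The last peak of replicate 2 ended between 7.67 kb (II) and 116.8 kb (IV) before it. The right ends were not tested. Fewer calls in replicate 2 are not excluded: at the rate at which replicate 1 peaks of like score had partners, the probability that no left-tip peak had one was 0.011, and 0.13 without the highest-scoring one. For the mitochondrial peaks it was 0.0029, and 0.59 without the higher-scoring one, and these peaks had been picked because replicate 2 lacks them. The combined list had no mitochondrial peak either, and its first peaks on I, II, IV and X started at 1945, 29178, 17275 and 2068, but 1 combined peak within 500 bp of a left end, on V starting at 164, argues against a blanket removal of left tips from that list; other differences in filtering, libraries or controls stay open, and no biological explanation was tested.

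The combined list held 2773 peaks that neither replicate had, so it is neither the union nor the intersection of these lists. Of them, 97.2% scored under the list's median, which a separate call on pooled reads that reaches weaker sites would also give. Combined peaks in 1 replicate only were weak too. Their median scores were 5.77 (replicate 1 only) and 6.105 (replicate 2 only), against 8.58 for the whole list. Low scores thus mark poorly shared peaks in general, so this share cannot tell how the list was made. The sources used here do not describe it.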
